A study of Homo sapiens with 310 samples.

How the data were processed

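The series holds 310 regions of human pancreas sections on 3 slides and 5 collection plates, profiled with the GeoMx whole-transcriptome probe set, and each region carries a label of its type. The authors deposited 1 table of counts per gene and region, whose values were taken to be expected counts (raw de-duplicated probe counts per gene, not normalised), and a file per region with its read totals and its counts per probe. Per the file headers, reads were processed with the GeoMx NGS Pipeline 2.3.3.10. The deposited gene rows hold whole numbers in every region, and only the row of negative probes, a summary of several probes, does not. The submitters' notes name hg38 and limma without saying for what they were used. The table has 378 columns, of which 68 match no sample of the series and were not used. No 2 columns were identical, and the highest correlation of log2 counts between 2 regions was 0.964. Genes are identified by symbol as in the table, of which 18388 of 18676 were in the RefSeq symbol table and 280 more matched as an older name, and the files give no positions. XIST, TSIX and Y-linked genes (23) were left out, leaving 18653.

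Each region's limit of quantitation was 2 times its negative probe value and at least 2 counts. A gene was kept where its count passed the limit in at least 10% of the regions of any 1 type compared. Total counts ran from 22519 to 7189158, apart from 1 region with a total of 8, which was below the minimum of 1000 and was not fitted by region. Levels are log2(CPM + 1), with CPM the count scaled to a common library size, with TMM factors. For single regions the total is over all genes, and for sums per slide and for the comparisons within 1 slide it is over the genes kept by the filter, so levels of the 2 kinds lie on different scales. Tests on single values are 2-sided permutation tests, exact where a group had fewer than 10 regions and with 100000 permutations otherwise, the smallest p of which is 1e-05.

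The labels name no donor, so the slide was taken as the unit, and that slides are independent is assumed. For IPMN, NormalDuct, Tumor, Stroma and Acinar, counts were summed per slide and type, which gave 14 columns, and tested in 1 fit with edgeR 4.0.16 (TMM scaling, quasi-likelihood F test, Benjamini-Hochberg adjusted p under 0.05) with the slide as a fixed block, which pairs the types within a slide. ADM, Nerve and Lymphoid each lie on 1 slide, so their regions were compared singly with Acinar or Stroma regions of that slide, and p-values over regions that may share donors are too small. Errors of log2 fold changes (SE) are the absolute fold divided by the square root of the test's F statistic. They restate the test and are no separate measure of spread. Errors of levels are standard deviations over slides or regions.

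The named genes of a comparison were chosen by a rule: the 10 largest rises and the 10 largest falls among genes past the threshold with the same sign on every slide that holds both types (for comparisons on 1 slide, with ranges that do not overlap), leaving out keratins, PTPRC, sex-linked genes and immunoglobulin and HLA genes. Up to 4 members of each list with the smallest adjusted p were added, and not every gene chosen in this way is named. The same holds for KRT17, MUC5AC, MUC6, MUC2, MUC1, S100A2, S100P, TFF1 and CFTR in epithelial comparisons whatever their p. The 20 gene lists were acinar, normal duct, gastric mucous, intestinal, classical tumour, basal-like tumour, keratins, cell cycle, basement membrane and invasion, fibroblast matrix, smooth muscle and pericyte, endothelial, Schwann and nerve, B and plasma cell, T and NK cell, myeloid cell, islet, interferon and antigen presentation, hypoxia and glycolysis, and immediate early and heat shock. Some lists share genes. AGR2, AGR3, CTSE, TFF1, TFF2, ANXA10, VSIG2 and TSPAN8 are on both the classical tumour and the gastric mucous list. LGALS4, TFF3, MYO1A, CDH17, SPINK4 and REG4 are on both the classical tumour and the intestinal list. Results of such lists are not independent. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with the correlation estimated within each list, and with fry, adjusted over the lists of a comparison. Median, mean and camera's direction differed in sign in 20 of 158 list tests, of which 1 passed camera's threshold, basement membrane and invasion in Nerve against Stroma.

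The comparisons, tests, lists, named genes and alternatives of the report were fixed before the data were examined, except for leaving out NormalDuct regions of plate 1. The tests of the closing parts were written on patterns noticed in these data. The alternatives were other scalings (median of ratios and upper quartile), other tests (DESeq2 1.42.0 and limma-voom), other filters on low counts, subtraction of the negative probe value, a fit of only the 2 types compared, no block for slide, regions as units with slide or plate as a block, mean log2 levels per slide, leaving out columns made from 1 region or regions with under 5% of genes above the limit, and leaving out each slide in turn or, in the comparisons within 1 slide, each ADM, Nerve or Lymphoid region. R 4.3.3 and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 were used.

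The tests were run on simulated counts with the dispersion of each comparison and 100 genes changed by 1 and 100 by 2 on the log2 scale. edgeR recovered 49% (Lymphoid against Stroma) to 100% (Nerve against Stroma) of the changes of 1 and 96% or more of those of 2. The changed genes were picked from those above the median fitted level, so recovery at lower levels was not measured. Regions were drawn as independent, so shared donors were not simulated. The share of false calls with edgeR was 5.18% for IPMN against NormalDuct, 10.3% for Tumor against IPMN, 9.23% for Tumor against NormalDuct, 10.4% for Stroma against IPMN and 5.35% for Acinar against NormalDuct, and 4.85%, 4.31% and 2.68% for ADM, Nerve and Lymphoid, so adjusted p-values near the threshold in 3 of these comparisons are too small. DESeq2 gave 4.33% to 17.7% false calls. In all 8 comparisons a list with planted changes was found and 0 other lists were called. The simulated genes were drawn independently and the other lists at random, so false list calls from correlation within a list were not tested.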

Results

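The deposited data hold counts of gene-specific probes from 310 outlined tissue regions of human pancreas, measured with the GeoMx Digital Spatial Profiler. This instrument releases probe barcodes from a chosen area of a tissue section and counts them by sequencing. The regions lie on 3 slides. The labels name 160 regions of intraductal papillary mucinous neoplasm (IPMN, a mucin-producing cystic neoplasm of the pancreatic ducts), 86 of Stroma, 18 of NormalDuct, 18 of Tumor, 11 of Acinar, 7 of Nerve, 4 of acinar-to-ductal metaplasia (ADM), 2 of Lymphoid, 2 of pancreatic intraepithelial neoplasia (PanIN) and 2 of chronic pancreatitis (ChronicPanc). The labels give neither the donor nor the grade nor the KRT17 status of a region, so regions may share donors. Epithelium was outlined with a pan-cytokeratin stain, so keratin transcripts are given but not read as differences between region types.

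Total counts per region ran from 22519 to 7189158 with a median of 437347, apart from 1 Stroma region of slide 3 with a total of 8. That region was left out of levels and fits of single regions, while its 8 counts entered the tested sum for Stroma of slide 3. Acinar regions of slide 1 were the deepest, with a median total of 6002150 over 5 regions, and NormalDuct regions of slide 3 had a median of 169921 over 7 regions. The median region had 15.41% of genes above its limit of quantitation and a sequencing saturation of 80.6%. On slide 2, NormalDuct and Tumor were represented by 1 region each. Levels are log2(CPM + 1), where CPM is the count scaled to a common library size. The scaling is relative to all genes for single regions and to the genes kept by the filter for sums per slide and for the comparisons within 1 slide. Over single regions the level of the negative probes averaged 5.05 ± 0.09 (SD, n = 10 regions) in NormalDuct of slide 1 and 4.91 ± 0.10 (SD, n = 7 regions) in NormalDuct of slide 3, so a single region's level near 5 is at background.

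**Figure D1:**
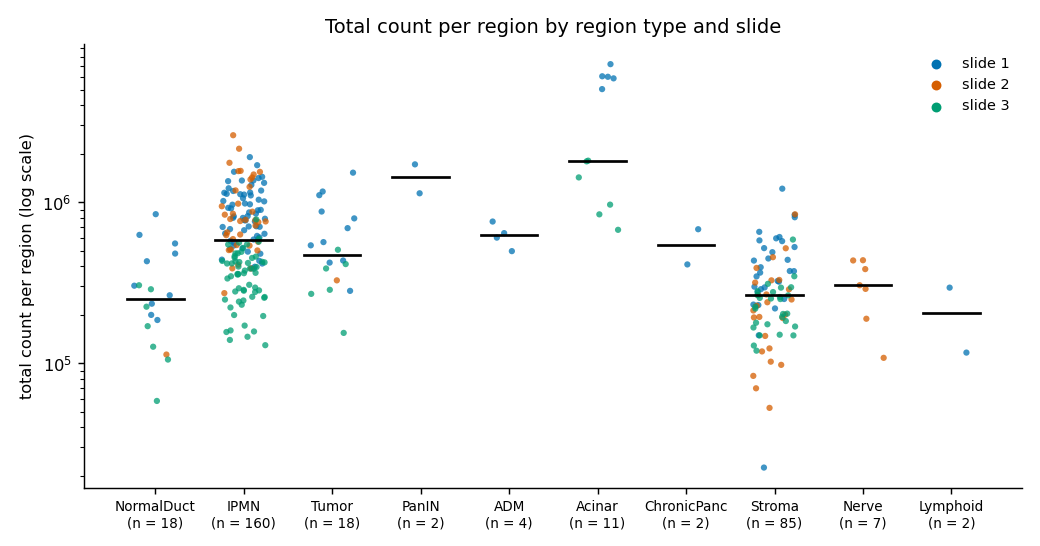
Total probe counts per region (log axis), by region type and slide, with 1 point per region. Totals ran from 22519 to 7189158 apart from 1 Stroma region with 8 counts.

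The series title names KRT17, a keratin of basal and injured epithelium. Its transcripts were followed across the epithelial types with 8 other fixed genes. KRT17 levels in the sums per slide varied between slides: IPMN had 8.48 on slide 1, 5.69 on slide 2 and 5.89 on slide 3. NormalDuct had 5.65, 7.33 and 5.86 on the same slides, and Tumor had 9.46, 5.93 and 6.14. Among single IPMN regions of slide 1, KRT17 spread from 4.64 to 10.11 with a mean of 7.08 ± 1.56 (SD, n = 64 regions), against 5.35 ± 0.61 on slide 2 (n = 37 regions) and 5.40 ± 0.82 on slide 3 (n = 59 regions). MUC2, the gel-forming mucin of intestinal goblet cells, reached 13.54 in IPMN of slide 2, against 5.75 on slide 1 and 6.37 on slide 3. MUC5AC, the gel-forming mucin of gastric surface cells, stood at 10.20, 10.14 and 12.13 in IPMN of slides 1, 2 and 3. MUC6, the mucin of gastric glands, stood at 9.90, 5.18 and 11.95 in IPMN, and at 12.62, 6.02 and 7.04 in NormalDuct. S100A2, a calcium-binding protein of squamous epithelium, did not pass the filter on low counts, and its sums averaged between 5.24 ± 0.12 in Acinar (SD, n = 2 slides) and 5.52 ± 0.26 in NormalDuct (SD, n = 3 slides) over the 5 summed types.

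**Figure D2:**
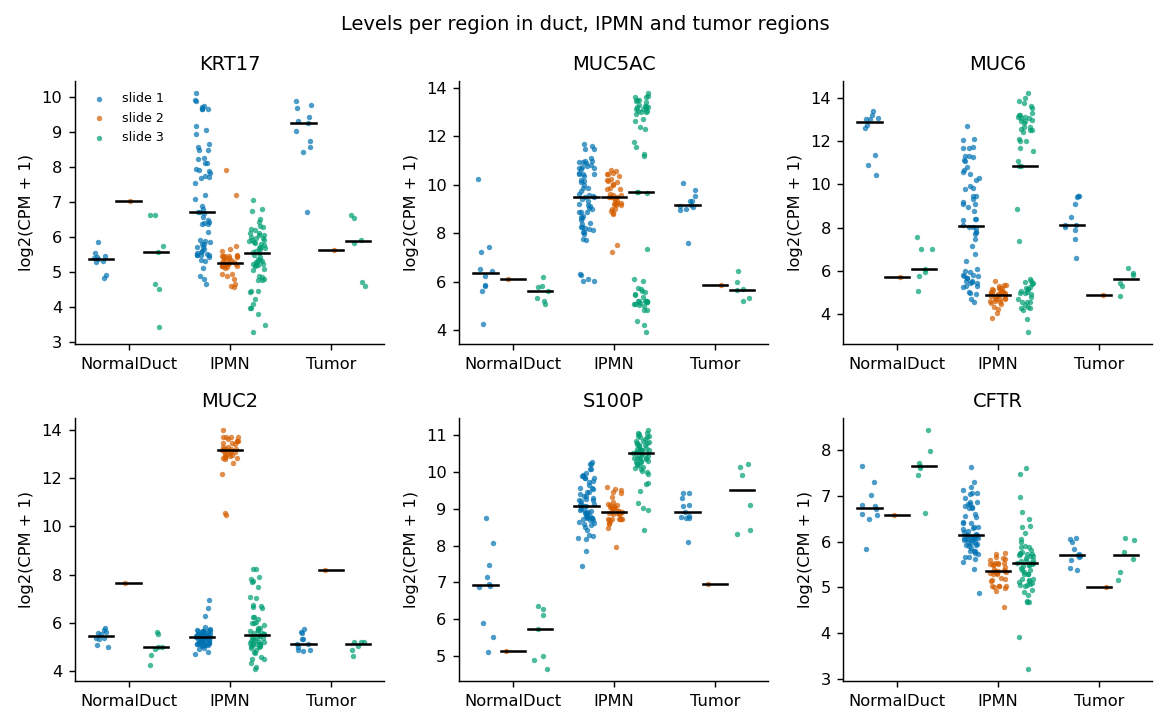
Levels of KRT17, MUC5AC, MUC6, MUC2, S100P and CFTR in log2(CPM + 1), 1 point per NormalDuct, IPMN and Tumor region, coloured by slide, with black lines at the medians. KRT17 spread from 4.64 to 10.11 over the IPMN regions of slide 1, and MUC2 was high in IPMN of slide 2.

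The first comparison asked which transcripts set IPMN epithelium apart from NormalDuct epithelium. Among the largest rises in IPMN, REG4, a secreted lectin of the intestinal epithelium, was higher by 4.23 ± 0.79 on the log2 scale (SE, adjusted p = 0.025). S100P, a calcium-binding protein, rose by 3.23 ± 0.60 (adjusted p = 0.024). CEACAM5, the carcinoembryonic antigen, rose by 2.90 ± 0.47 and CLDN18, a tight-junction protein of gastric epithelium, by 2.39 ± 0.53. Transcripts of duct cells were lower in IPMN: FXYD2, a regulatory subunit of the sodium pump, fell by 3.53 ± 0.34 (SE, adjusted p = 0.00031). CFTR, the chloride channel of duct cells, fell by 1.43 ± 0.29 (adjusted p = 0.032). CD55, a membrane inhibitor of complement, averaged 8.99 ± 0.19 in IPMN and 6.48 ± 0.33 in NormalDuct (SD, n = 3 slides each), a rise of 2.61 ± 0.28 (SE, adjusted p = 0.00042).

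Of the 11358 genes tested with edgeR on sums per slide and type, 62 were higher and 77 lower in IPMN than in NormalDuct, and 1710 had an unadjusted p under 0.05. The remaining genes with the largest rises were S100A16 (1.93 ± 0.20), MUC13, a membrane mucin (1.90 ± 0.28), FXYD3 (1.98 ± 0.43), PLAC8 (2.05 ± 0.46) and SH3BGRL3 (1.77 ± 0.27). CRISP3 fell by 3.36 ± 0.51 and SERPING1, the inhibitor of complement C1, by 2.61 ± 0.38. CES1, a carboxylesterase, fell by 2.35 ± 0.35, CLU, the secreted chaperone clusterin, by 2.33 ± 0.49, and SCGB3A1, a secretoglobin, by 2.21 ± 0.11. GHRL, the ghrelin precursor, CHST4, a sulfotransferase, TM4SF4 and APCDD1, a Wnt inhibitor, fell by 2.08 ± 0.17, 2.08 ± 0.26, 2.05 ± 0.38 and 2.01 ± 0.21. Each of these genes had the same sign of fold on all 3 slides. The mucins varied by slide and did not pass. MUC5AC differed by 4.06 ± 0.97 (adjusted p = 0.062), MUC2 by 3.06 ± 1.05 (adjusted p = 0.18). MUC6 differed by -0.06 ± 1.51 (adjusted p = 1) and MUC1 by -0.18 ± 0.74 (adjusted p = 0.98). KRT17 differed by 0.87 ± 0.79 (adjusted p = 0.68), with slide folds of 2.83, -1.64 and 0.03. TFF1, a gastric trefoil peptide, differed by 2.85 ± 0.80 (adjusted p = 0.11).

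Among the fixed gene lists, 10 of 25 normal duct genes fell and 0 rose. In this list 17 fell and 2 rose when adjusted over the list alone (camera adjusted p = 5.65e-25, adjusted p = 0.0245 with an estimated correlation). SCTR, the secretin receptor, fell by 1.18 ± 0.16, PKHD1, a protein of the primary cilium, by 1.35 ± 0.19 and SLC3A1, an amino acid transporter subunit, by 1.67 ± 0.25. The classical tumour list had 3 of 23 genes higher and 14 when adjusted over the list alone (camera adjusted p = 8.95e-14, adjusted p = 0.0245 with an estimated correlation), with REG4, ST6GALNAC1 (1.16 ± 0.24) and PLA2G10 (0.94 ± 0.20) called. The gastric mucous list had 3 of 26 genes higher, and 13 higher and 1 lower when adjusted over the list alone, with CREB3L1 (1.63 ± 0.29) beside S100P and CLDN18 (adjusted p = 0.195 with an estimated correlation). NormalDuct regions of slide 1 themselves held transcripts of gastric glands, with PGC, the precursor of pepsin C, at 12.89 ± 3.35 (SD, n = 10 regions) against 6.11 ± 1.09 in those of slide 3 (SD, n = 7 regions). Both the gastric mucous and the intestinal list share genes with the classical tumour list, REG4 being on the latter 2. The intestinal list had 3 of 21 genes higher and 1 lower, and 9 higher and 1 lower when adjusted over the list alone (adjusted p = 0.189 with an estimated correlation). The lower member was ANPEP, an aminopeptidase of brush borders, which fell by 1.75 ± 0.36. In the list of basement membrane and invasion, 2 of 26 genes rose, and 6 rose and 2 fell when adjusted over the list alone, with COL17A1 at 1.31 ± 0.25 and the laminin receptor subunit ITGA6 at 0.93 ± 0.15 (adjusted p = 0.597 with an estimated correlation). The acinar list had 0 of 34 members called and a median of -0.72. Its camera call, like those of the cell cycle, fibroblast matrix, myeloid cell and islet lists, was lost with an estimated correlation (adjusted p = 0.597 for each).

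The count of genes past the threshold depended on the slides: it was 255 without slide 1, 82 without slide 2 and 1 without slide 3. A fit of only the 2 types compared called 5 genes, and leaving out columns made from 1 region called 22. A total of 210 genes passed without the NormalDuct regions of collection plate 1, an alternative chosen after seeing the data.

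The second comparison asked what separates Tumor regions from IPMN. The largest rise in Tumor was in DMBT1, a mucosal scavenger glycoprotein, which was higher by 2.77 ± 0.45 (SE, adjusted p = 0.047). SERPINA3, an acute-phase protease inhibitor, rose by 2.25 ± 0.36 (adjusted p = 0.047) and PI3, the elastase inhibitor elafin, by 2.10 ± 0.23 (adjusted p = 0.0049). CXCL5, a chemokine that attracts neutrophils, rose by 1.77 ± 0.26, from a mean of 5.94 ± 0.27 in IPMN to 7.59 ± 0.79 in Tumor (SD, n = 3 slides each). TNFAIP2, a gene induced by tumour necrosis factor, rose by 1.36 ± 0.22, MELTF, melanotransferrin, by 1.01 ± 0.15 and STMN1, the microtubule-destabilizing protein stathmin, by 0.75 ± 0.12. FAM177B fell by 1.72 ± 0.23 (SE, adjusted p = 0.027). These 7 higher genes and 1 lower gene were all that passed of 11358 tested with edgeR, while 857 genes had an unadjusted p under 0.05. All 8 had the same sign on each of the 3 slides.

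No list member passed the test over all genes, and lists were counted when adjusted over the list alone. The classical tumour list had 5 of 23 genes lower and 0 higher in Tumor, with a median of -0.54 (camera adjusted p = 2.94e-14, adjusted p = 0.0369 with an estimated correlation). The gastric mucous list had 5 of 26 lower and 0 higher and the intestinal list 7 of 21 lower and 1 higher (adjusted p = 0.157 with an estimated correlation for both). Both share genes with the classical tumour list, so these are not separate results. MUC5AC differed by -3.43 ± 0.94 (adjusted p = 0.29), MUC2 by -3.02 ± 1.02 (adjusted p = 0.42). MUC6 differed by -2.98 ± 1.52 (adjusted p = 0.72) and TFF1 by -1.95 ± 0.80 (adjusted p = 0.58), none past the threshold. In the fibroblast matrix list 10 of 27 genes were higher and 0 lower, and in the list of basement membrane and invasion 8 of 26 were higher and 0 lower (adjusted p = 0.157 with an estimated correlation for both). The list of interferon and antigen presentation had a positive fold in 23 of 23 genes, with 3 higher when adjusted over the list alone and a median of 0.52 (adjusted p = 0.275 with an estimated correlation). The basal-like tumour list had 1 of 11 genes higher (camera adjusted p = 0.090) and the cell cycle list 0 of 22 (camera adjusted p = 0.0016, adjusted p = 0.637 with an estimated correlation). KRT17 differed by 0.81 ± 0.63 (adjusted p = 0.92) and S100P by -0.97 ± 0.52 (adjusted p = 0.74). MUC1 differed by -0.35 ± 0.66 (adjusted p = 1) and CFTR by -0.24 ± 0.29 (adjusted p = 1).

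Few genes separated Tumor from IPMN in the sums per slide: limma-voom called 0, against 8 with edgeR and 90 with DESeq2. In data simulated for this comparison 10.3% of edgeR's calls were false. Without slide 1 the count was 17, without slide 2 it was 4 and without slide 3 it was 0. Fits on single regions, whose p-values are too small where regions share donors, called 1781 to 1938 genes.

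The third comparison set Tumor against NormalDuct. In Tumor, CD55 rose by 2.52 ± 0.28 (SE, adjusted p = 0.001) and IL32, an inflammatory cytokine, by 2.56 ± 0.52 (adjusted p = 0.024). GPRC5A, a membrane receptor of epithelia, rose by 2.35 ± 0.45 (adjusted p = 0.021) and CEACAM5 by 2.35 ± 0.47 (adjusted p = 0.023). CLU was at 6.06 ± 0.91 in Tumor and 10.08 ± 0.64 in NormalDuct (SD, n = 3 slides each) and fell by 4.02 ± 0.54 (SE, adjusted p = 0.0039). FXYD2 fell by 3.67 ± 0.36 (adjusted p = 0.00042), and the stress-responsive kinase gene SGK1 and phosphatase gene DUSP1 by 2.33 ± 0.45 (adjusted p = 0.021) and 2.37 ± 0.56 (adjusted p = 0.039).

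With edgeR, 335 genes of 11358 tested passed, of which 213 were higher in Tumor, and 2242 had an unadjusted p under 0.05. With upper quartile scaling the split was 168 higher and 216 lower. Other large rises were in CLDN18 (2.24 ± 0.52), LAMA3, a laminin of the basement membrane (1.79 ± 0.38), PI3 (1.80 ± 0.31) and the histone genes H1-5 (2.28 ± 0.55) and H4C12 (2.16 ± 0.50), whose probes may not tell copies of the family apart. ANPEP, UGT2B15, a steroid-conjugating enzyme, and CES1 fell by 2.58 ± 0.41, 2.39 ± 0.42 and 2.43 ± 0.41. SERPING1 and GHRL fell by 2.32 ± 0.40 and 2.27 ± 0.21 and CRISP3 fell by 3.27 ± 0.64. All genes named so far in this comparison had the same sign on each of the 3 slides, which the rule for naming them required. Of all 335 called genes, 290 had it. The normal duct list had 12 of 25 genes lower and 1 higher, and 17 lower and 1 higher when adjusted over the list alone (camera adjusted p = 1.21e-23, adjusted p = 0.0506 with an estimated correlation). It included SLC3A1 (-1.98 ± 0.27), the bicarbonate transporter gene SLC4A4 (-1.92 ± 0.27), CFTR (-1.67 ± 0.31) and SCTR (-1.22 ± 0.18). In the list of basement membrane and invasion 5 of 26 genes rose and 0 fell, and 13 rose when adjusted over the list alone, with the integrin genes ITGA2 at 1.14 ± 0.18 and ITGA6 at 1.08 ± 0.16 (adjusted p = 0.277 with an estimated correlation).

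The list of interferon and antigen presentation had 4 of 23 genes higher in Tumor than in NormalDuct and 6 when adjusted over the list alone. The 4 were IFI6 (1.38 ± 0.22), TAP1, the peptide transporter of antigen presentation (1.09 ± 0.26), PSMB8, an immunoproteasome subunit (0.98 ± 0.18), and ISG15 (0.78 ± 0.18), with folds positive in 23 of 23 (adjusted p = 0.753 with an estimated correlation). The fibroblast matrix list had 3 of 27 genes higher and 4 when adjusted over the list alone, with the collagen genes COL3A1 at 1.34 ± 0.25 and COL1A1 at 1.16 ± 0.23 and SPARC at 1.18 ± 0.26 (camera adjusted p = 0.12). The cell cycle list had 0 of 22 members called (camera adjusted p = 9.28e-05, adjusted p = 0.753 with an estimated correlation). The acinar list had 0 of 34 called with a median of -0.88 (adjusted p = 0.832 with an estimated correlation), and the islet list 0 of 14, with 3 lower when adjusted over the list alone (adjusted p = 0.753 with an estimated correlation). Of the hypoxia and glycolysis list only PFKFB3, a regulator of glycolysis, passed, at -1.79 ± 0.37, and of the basal-like tumour list only TNS4, at 1.27 ± 0.32. The gastric mucous list had 1 of 26 genes higher, with a median of 0.41 and a mean of -0.00096, so these differed in sign. KRT17 differed by 1.68 ± 0.83 (adjusted p = 0.28) with slide folds of 3.80, -1.40 and 0.28. S100P differed by 2.26 ± 0.58 (adjusted p = 0.055) and MUC5AC by 0.63 ± 0.85 (adjusted p = 0.75). MUC6 differed by -3.04 ± 1.41 (adjusted p = 0.25) and MUC2 by 0.04 ± 0.88 (adjusted p = 0.99). For MUC1 the difference was -0.53 ± 0.72 (adjusted p = 0.75) and for TFF1 0.89 ± 0.75 (adjusted p = 0.56).

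Both neoplastic types were compared with the same NormalDuct sums, and 27 of the higher genes and 63 of the lower genes were called in both comparisons. This compares with 1.16 and 0.827 if the calls were independent and 0 in each of 20 simulations with no true change. The simulations leave out the effects and the independent value leaves out the shared sums, so neither gives the overlap that chance would give here. The NormalDuct sums cannot be split between the comparisons, so their own variation enters both. Without slide 1 the count for Tumor against NormalDuct was 1.3e+02 to 2 digits, without slide 2 it was 423 and without slide 3 it was 1, and a fit of only the 2 types called 43 genes.

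**Figure D3:**
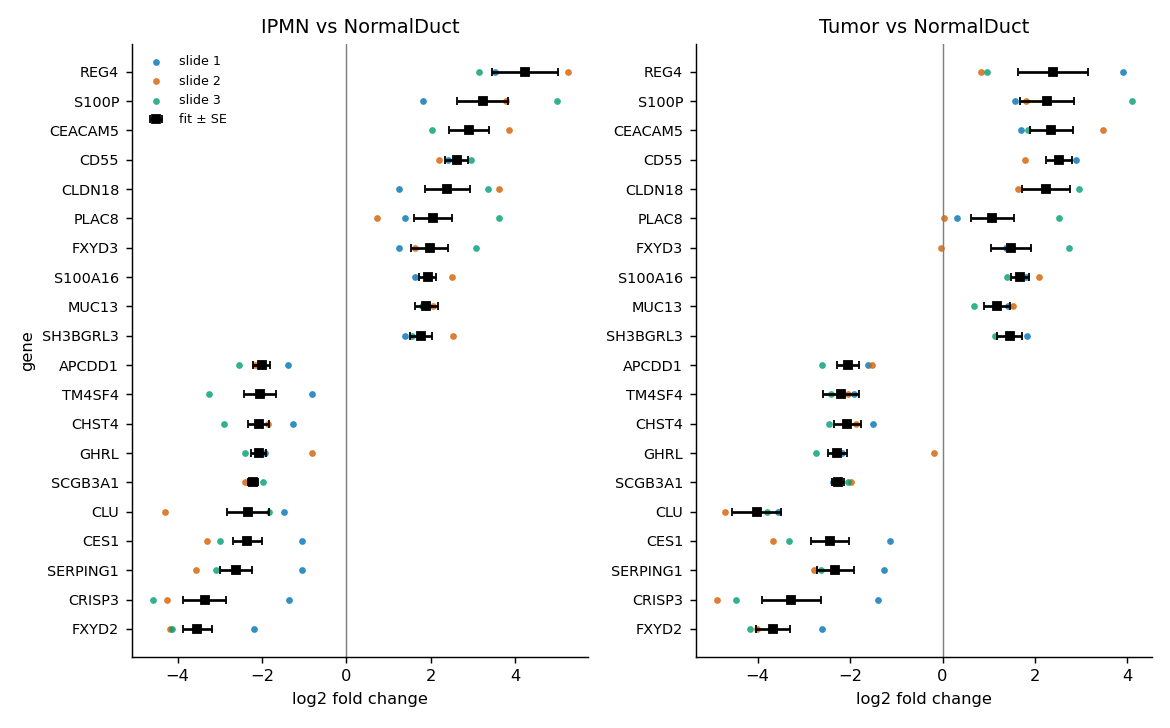
Fitted log2 fold changes (squares, bars ± SE) and folds per slide (dots) in IPMN and in Tumor against NormalDuct, for the 10 largest rises and falls in IPMN. FXYD2 lay at -3.53 in IPMN and -3.67 in Tumor.

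Stroma was compared with IPMN to describe the surrounding tissue. Stroma held the transcripts of fibroblasts and plasma cells: COL3A1, a fibrillar collagen, was higher by 4.11 ± 0.24 (SE, adjusted p = 3.5e-07), SPARC, a matrix protein, by 3.74 ± 0.24 (adjusted p = 4.5e-07) and JCHAIN, the joining chain of secreted antibodies, by 4.50 ± 0.45 (adjusted p = 1.1e-05). The largest falls in Stroma were in TFF2 (fell by 5.31 ± 1.19), TFF1 (fell by 5.0 ± 0.85), MUC5AC (fell by 4.97 ± 0.95, adjusted p = 0.0016) and AGR2, a folding factor for mucins (fell by 4.58 ± 0.70). MUC5AC averaged 6.09 ± 0.20 in Stroma and 10.82 ± 1.14 in IPMN (SD, n = 3 slides each).

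With edgeR, 1464 of 11358 genes were higher and 1643 lower in Stroma, 47.12% of the calls being higher. With upper quartile scaling the split was 2366 and 1233, or 65.74% higher. Other large rises were in IGFBP7 (3.82 ± 0.28), the complement genes C3 (3.82 ± 0.48) and C1R (3.43 ± 0.25), MGP (3.71 ± 0.27), COL1A2 (3.66 ± 0.26), VIM, the mesenchymal filament vimentin (3.63 ± 0.22), and DCN, the proteoglycan decorin (3.19 ± 0.21). REG4, LGALS4, FXYD3, CEACAM1, TFF3 and TSPAN8, all products of gut or duct epithelium, differed by -4.39 ± 0.78, -3.85 ± 0.40, -3.80 ± 0.44, -3.74 ± 0.57, -3.73 ± 0.72 and -3.72 ± 0.43. Folds of these genes had the same sign on all 3 slides, which the rule for naming them required. Of all 3107 called genes, 3062 had it.

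In the fibroblast matrix list 25 of 27 genes rose and 0 fell, and 26 rose when adjusted over the list alone (adjusted p = 0.00344 with an estimated correlation). Immune lists were higher as well: 10 of 13 B and plasma cell genes, 17 of 17 T and NK cell genes and 17 of 18 myeloid cell genes rose. The counts were 13, 17 and 17 when adjusted over the list alone (adjusted p = 0.00344, 0.00544 and 0.00344 with an estimated correlation). Examples were TRBC1, a T cell receptor constant region (2.02 ± 0.16), IL7R (2.02 ± 0.15), the complement gene C1QC of macrophages (1.84 ± 0.13) and CD163, a scavenger receptor of macrophages (1.28 ± 0.08). In the endothelial list 12 of 13 genes rose, with PECAM1 at 1.31 ± 0.09, and in the list of smooth muscle and pericytes 11 of 13, with ACTA2, smooth muscle actin, at 1.68 ± 0.14. In both lists 12 rose when adjusted over the list alone (adjusted p = 0.00344 and 0.0365 with an estimated correlation). The classical tumour list had 21 of 23 genes lower and 23 when adjusted over the list alone (adjusted p = 0.0129 with an estimated correlation). The gastric mucous list had 20 of 26 lower and 20 over the list alone, and the intestinal list 12 of 21 lower and 14 over the list alone (adjusted p = 0.146 and 0.190 with an estimated correlation). Both share genes with the classical tumour list. The Schwann and nerve list had 6 of 10 genes higher and 1 lower, ERBB3, a receptor that epithelia also express, at -1.45 ± 0.16 (adjusted p = 0.369 with an estimated correlation). In the list of basement membrane and invasion 8 of 26 genes rose, among them VIM, and 9 fell, among them ITGA6 at -0.93 ± 0.12, with a median of -0.37 against a positive direction of camera's test (adjusted p = 0.78). The islet list had 3 of 14 genes higher, the list of interferon and antigen presentation 3 of 23 higher and 1 lower, and that of hypoxia and glycolysis 2 of 18 higher and 6 lower, with camera adjusted p of 0.17, 0.35 and 0.28. Keratins, the family stained to outline the epithelium, had 5 of 9 genes lower (adjusted p = 0.369 with an estimated correlation). Without slide 3 the count of 3107 genes was 1211, and limma-voom called 1152.

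Acinar regions, which lie on slides 1 and 3, were compared with NormalDuct. Transcripts of digestive enzymes led the difference: CTRB1, chymotrypsinogen B, was higher by 8.34 ± 1.42 (SE, adjusted p = 0.0039), CEL, a lipase, by 7.45 ± 1.26 (adjusted p = 0.0039) and CPA1, a carboxypeptidase, by 8.09 ± 1.57 (adjusted p = 0.0085). NormalDuct held more PIGR, the receptor that carries antibodies across epithelium, which fell by 5.22 ± 0.61 in Acinar regions (adjusted p = 0.00026), MUC5B, a gel-forming mucin (fell by 3.62 ± 0.59), and ANXA4, an annexin of duct cells (fell by 3.06 ± 0.38). Acinar transcripts were also present in NormalDuct of slide 3, where the acinar list averaged 8.59 ± 0.47 over single regions (SD, n = 7) against 5.46 ± 0.15 on slide 1 (SD, n = 10).

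With edgeR, 352 genes were higher and 261 lower of 11358 tested, and 1977 had an unadjusted p under 0.05. CELA3A and CELA3B, elastases whose probes may not tell the copies apart, rose by 9.02 ± 1.92 and 7.35 ± 1.16, and likewise PRSS2, a trypsinogen (8.69 ± 2.15), and AMY1A, an amylase (7.38 ± 1.39). CLPS, colipase, CPB1, a carboxypeptidase, and PNLIP, pancreatic lipase, rose by 8.45 ± 1.65, 8.42 ± 1.88 and 8.20 ± 1.64. LYZ, lysozyme, fell by 5.36 ± 1.39 and S100A6, a calcium-binding protein, by 4.25 ± 0.67. AGR2 fell by 3.58 ± 0.82, CRISP3 by 3.13 ± 0.60, RHOB by 2.98 ± 0.67, ID1 by 2.97 ± 0.79 and CEACAM1 by 2.82 ± 0.68. These folds had the same sign on both slides, which the rule for naming the genes required. All 613 called genes had it as well. In the acinar list 30 of 34 genes rose and 0 fell, and 33 rose when adjusted over the list alone (camera adjusted p = 1.4e-82, adjusted p = 0.0195 with an estimated correlation), with rises in the acinar transcription factors BHLHA15 (2.61 ± 0.14) and RBPJL (2.63 ± 0.17). The normal duct list had 10 of 25 genes lower and 14 when adjusted over the list alone (adjusted p = 0.120 with an estimated correlation), with the duct transcription factor SOX9 at -1.68 ± 0.27. The classical tumour and gastric mucous lists, which share genes, had 5 of 23 and 4 of 26 genes lower, and 11 and 10 when adjusted over the list alone (adjusted p = 0.120 and 0.353 with an estimated correlation). Among immediate early and heat shock genes 1 of 20 fell, ZFP36, at -2.50 ± 0.60, and 3 when adjusted over the list alone (adjusted p = 0.353 with an estimated correlation). INS, insulin, was at 2.95 ± 0.58 among 2 of 14 islet genes that rose (adjusted p = 0.353 with an estimated correlation). The list of interferon and antigen presentation had 2 of 23 genes lower (adjusted p = 0.490 with an estimated correlation). Fibroblast matrix and endothelial genes had 2 of 27 and 2 of 13 higher, and keratins 2 of 9 lower (adjusted p = 0.490, 0.449 and 0.445 with an estimated correlation). Without slide 3 the count of 613 genes was 1.1e+02 to 2 digits, and a fit of only the 2 types called 274.

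ADM, a lesion in which acinar cells take on duct features, was compared with Acinar on slide 1, with 4 and 5 regions. ADM had fewer enzyme transcripts: CPA1 fell by 6.60 ± 1.39 (SE, adjusted p = 0.0013), from 15.77 ± 0.22 in Acinar to 7.95 ± 2.25 in ADM (SD). GP2, a zymogen granule protein, fell by 5.82 ± 0.81 (adjusted p = 2.4e-05). Transcripts of islet cells were higher in ADM, with GCG, glucagon, at 5.03 ± 0.68 (adjusted p = 2e-05) and SST, somatostatin, at 4.92 ± 0.51 (adjusted p = 1.1e-06), and so were matrix transcripts such as COL3A1 (2.84 ± 0.29) and MGP (2.58 ± 0.20). These regions may share donors, so the p-values are too small.

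In ADM, 614 of 3825 genes tested with edgeR were higher and 604 lower than in Acinar regions. Median totals were 622398 in ADM and 6002150 in Acinar of slide 1, with 64.7% and 44.5% of counts at background, 11.4% and 5.93% of genes above the limit and 4.45% and 34.3% of counts in the 10 most abundant genes. The folds were not separated from these differences. The acinar list had 31 of 33 genes lower and 32 when adjusted over the list alone (adjusted p = 0.084 with an estimated correlation), including BHLHA15, a transcription factor of acinar cells, at -2.51 ± 0.14. Other falls were in CELA2A (-6.38 ± 0.97), AMY1A (-6.36 ± 1.38), PNLIP (-6.15 ± 1.46), SYCN, syncollin (-5.97 ± 0.90), CLPS (-5.96 ± 1.54) and PLA2G1B, a phospholipase (-5.78 ± 1.05). The islet list had 17 of 19 genes higher and 18 when adjusted over the list alone (adjusted p = 0.291 with an estimated correlation), with CHGA, a secretory granule protein, at 3.15 ± 0.41, PCSK1N at 3.27 ± 0.44 and TTR at 3.91 ± 0.59. In the fibroblast matrix list 19 of 22 genes rose (adjusted p = 0.084 with an estimated correlation), with DCN at 2.3 ± 0.18, and in the endothelial list 5 of 7, with ENG at 1.44 ± 0.14 (adjusted p = 0.084 with an estimated correlation). Interferon and antigen presentation genes had 10 of 12 higher and smooth muscle and pericyte genes 6 of 10 (adjusted p = 0.200 and 0.450 with an estimated correlation). The normal duct list did not rise as a set: 1 of 13 genes was higher and 6 were lower, among them CFTR at -0.78 ± 0.15 and DEFB1, a defensin, at -2.19 ± 0.17 (camera adjusted p = 0.054).

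Nerve regions were compared with Stroma on slide 2, with 7 and 26 regions. Nerve held Schwann cell transcripts: SOX10, the transcription factor of the glial lineage, was higher by 2.94 ± 0.13 (SE, adjusted p = 2.8e-27), S100B, a calcium-binding protein of glia, by 2.89 ± 0.15 and NGFR, the low-affinity nerve growth factor receptor, by 2.25 ± 0.13. APOD, a lipid carrier found in nerve, rose by 3.76 ± 0.25, from 7.84 ± 0.87 in Stroma to 11.78 ± 0.37 in Nerve (SD). MGP, a matrix protein, fell by 3.65 ± 0.28 and BGN, the proteoglycan biglycan, by 3.23 ± 0.32. Regions may share donors, which makes these p-values too small.

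With edgeR, 350 of 8034 genes were higher in Nerve and 481 lower. Nerve regions had a median of 75.6% of counts at background and 8.76% of genes above the limit, against 66.3% and 13.5% in Stroma of slide 2. The lower levels in Nerve were not separated from this difference in quality. The Schwann and nerve list had 18 of 19 genes higher and 19 when adjusted over the list alone (adjusted p = 7.76e-12 with an estimated correlation), and LGI4 (2.82 ± 0.13), CHL1 (2.33 ± 0.12), ITGB8 (3.17 ± 0.13), PRIMA1 (2.47 ± 0.12) and SEMA3B (2.33 ± 0.13) were other large rises. In the list of basement membrane and invasion 7 of 19 genes rose, with ITGB4 at 1.91 ± 0.13 and the adhesion molecule gene L1CAM at 1.5 ± 0.16, and 3 fell. Its median was -0.02 while its mean was 0.19 (camera adjusted p = 0.000898, adjusted p = 0.0175 with an estimated correlation). The fibroblast matrix list had 20 of 26 genes lower and 1 higher and the endothelial list 5 of 10 lower (adjusted p = 0.0223 and 0.0175 with an estimated correlation), with MMP2, a matrix protease, at -1.79 ± 0.25 and PECAM1 at -0.74 ± 0.16. Plasma cell transcripts were lower, with JCHAIN at -5.01 ± 0.88, and 8 of 17 genes of the B and plasma cell list fell (adjusted p = 0.169 with an estimated correlation). In the T and NK cell and myeloid cell lists 5 of 16 and 2 of 17 genes fell (adjusted p = 0.403 and 0.456 with an estimated correlation). Immediate early genes were lower, with 8 of 15 called, among them the transcription factor gene FOS at -2.42 ± 0.36 and DUSP1 at -2.22 ± 0.24 (adjusted p = 0.0652 with an estimated correlation). The classical tumour and intestinal lists, which share genes such as TFF3, had 6 of 11 and 5 of 17 genes lower (adjusted p = 0.169 and 0.403 with an estimated correlation), with TFF3 at -1.38 ± 0.37 and MUC2 at -1.92 ± 0.52.

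Lymphoid was compared with Stroma on slide 1, with 2 and 31 regions. B2M, the light chain of class I antigen-presenting molecules, fell by 4.66 ± 0.59 (SE, adjusted p = 1.1e-07), CD74, the invariant chain of class II molecules, by 3.64 ± 0.66 (adjusted p = 8.1e-05) and TRBC1 by 2.17 ± 0.56 (adjusted p = 0.006). MS4A1, the B cell marker CD20, was at 4.83 and CD3E, a T cell receptor subunit, at 4.71 on average over the 2 regions, near their background of 5.05, on the scale of single regions. Matrix transcripts were lower too, with COL3A1 at -4.36 ± 0.84 and TIMP1, a protease inhibitor, at -4.48 ± 0.93. Lymphoid regions had a median of 70.9% of counts at background, against 64.7% in Stroma of slide 1. Neither rises nor falls in Lymphoid were separated from this difference in quality. The p-values over regions are too small where regions share donors, and 1 arm holds 2 regions.

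Of 6737 genes tested with edgeR, 297 were higher and 513 lower in Lymphoid, 36.7% of the calls being higher. With the median-of-ratios scaling the split was 402 and 437, or 47.9% higher. With the negative probe value subtracted 12.6% of the calls were higher, and with DESeq2 55.5%. The share of rises among the calls thus depended on the processing. The genes with the largest rises were ATRX, a chromatin remodeller (2.14 ± 0.19), KCNK4, a potassium channel (2.11 ± 0.16), PTBP1, a splicing regulator (1.98 ± 0.35), CCDC13 (1.87 ± 0.21) and KIR3DL1, a receptor of NK cells whose probes may not tell the family's copies apart (1.81 ± 0.21). In the B and plasma cell list 1 of 15 genes rose and 2 fell, and in the T and NK cell list 3 of 18 fell (camera adjusted p = 0.98 and 0.10). The myeloid cell list had 1 of 14 genes higher and 5 lower (adjusted p = 0.480 with an estimated correlation). The list of interferon and antigen presentation had 9 of 19 genes lower, the fibroblast matrix list 12 of 26 and the immediate early and heat shock list 9 of 17 (adjusted p = 0.0602, 0.0602 and 0.0648 with an estimated correlation). Hypoxia and glycolysis genes had 2 of 12 lower and keratins 1 of 6 higher (adjusted p = 0.0602 with an estimated correlation for both). The count of 810 genes was 217 without Lymphoid replicate 1 and 561 without replicate 2.

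**Figure D4:**
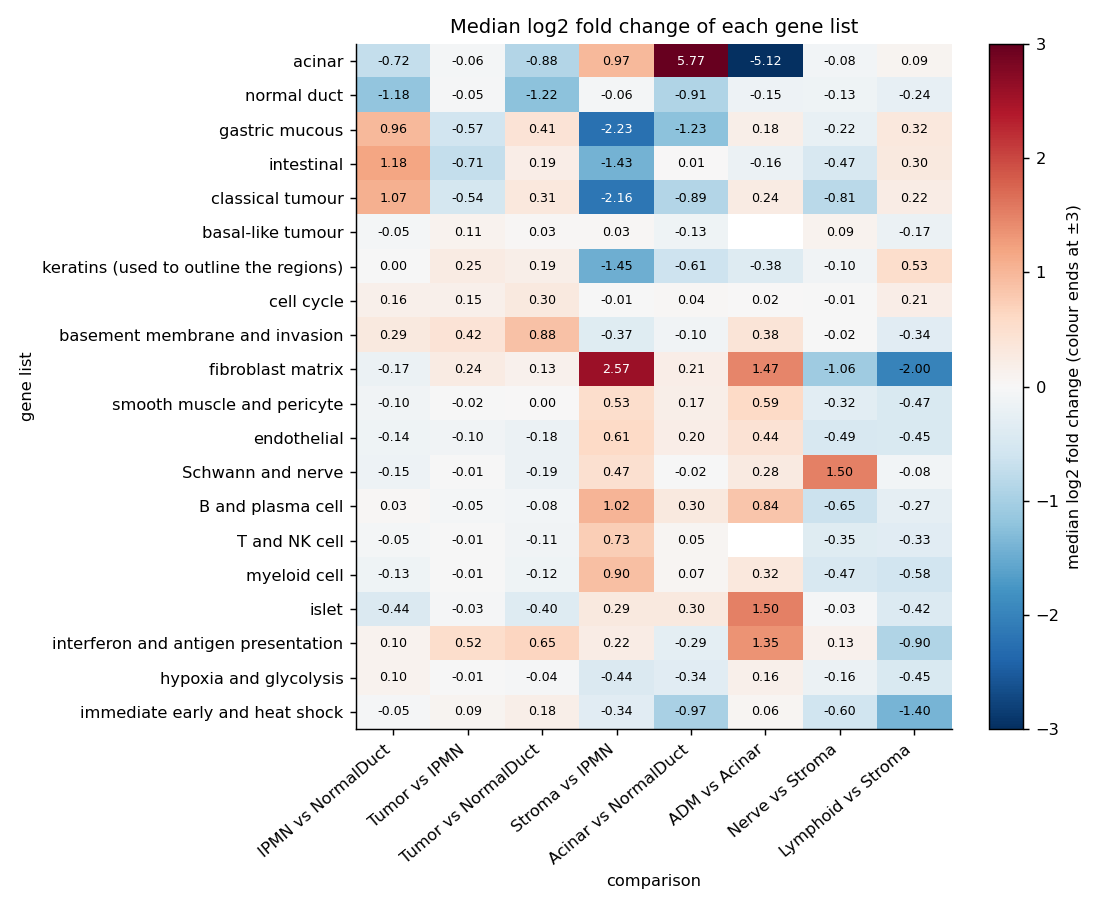
Median log2 fold change of the 20 fixed gene lists (lines of the heatmap) in the 8 comparisons (columns). The acinar list had a median of 5.77 in Acinar against NormalDuct and -5.12 in ADM against Acinar.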

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

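The comparison of PGC and MUC6 between NormalDuct and IPMN regions of slide 1 was chosen only after the result was seen, while the other tests of this part were written before their results.

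The folds of 8 fixed genes were compared between slides 1 and 3 with an interaction term in edgeR fitted to single regions, whose p-values are too small where regions share donors, and 11 of the 16 differences passed. Between IPMN and NormalDuct, the fold on slide 3 minus that on slide 1 was 8.32 for MUC6 (adjusted p = 2.05e-05), 4.21 for MUC5AC (adjusted p = 0.0035), 2.90 for S100P (adjusted p = 3e-11), 2.43 for TFF1 (adjusted p = 0.00013), -1.68 for CFTR (adjusted p = 7.06e-07) and -2.58 for KRT17 (adjusted p = 0.0035). KRT17 thus had a fold of 2.55 on slide 1 and -0.03 on slide 3 in this fit. Of the 59 IPMN regions of slide 3, 27 had MUC5AC between 3.91 and 7.34 and 28 had MUC6 at or below 8.85. Folds of these genes on slide 3 therefore average over separate sets of IPMN regions. Between Tumor and IPMN, the difference was -5.72 for MUC5AC (adjusted p = 0.0003), -5.26 for MUC6 (adjusted p = 0.0035), -2.71 for TFF1 (adjusted p = 2e-05), 0.81 for CFTR (adjusted p = 0.043) and -0.63 for S100P (adjusted p = 0.044).

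The MUC6 difference goes with gastric gland transcripts in NormalDuct of slide 1, where PGC exceeded NormalDuct of slide 3 by 6.77, MUC6 by 6.03 and TFF2 by 5.66, and FXYD2 differed by -3.20 (n = 10 and 7 regions), on genes picked because they showed it. RNA from IPMN cells with the mean levels of their type, in or beside these ducts, is argued against, since PGC was 2.77 higher (permutation p = 0.0084) and MUC6 4.22 higher in NormalDuct than in IPMN of the same slide, while MUC5AC differed by -2.81. Single IPMN regions of slide 1 reached 14.81 for PGC and 12.72 for MUC6, so RNA from such regions is not excluded by these means. PGC differed by 4.34 between plates 1 and 2 in NormalDuct regions (exact permutation p = 0.00476, n = 6 and 4 regions). In IPMN regions it differed by 0.23 (10.20 ± 3.11 and 9.96 ± 2.78, SD, n = 41 and 23 regions, permutation p = 0.768). This argues against a plate difference as large as that of the ducts acting on both types. The spread in IPMN is too wide to exclude a smaller one, and a plate difference in the ducts alone was not tested. The design names no group that separates these ducts, so no biological explanation was tested. A gland-like or metaplastic change of the ducts, a donor's difference or a NormalDuct label that is wrong for these regions may underlie the pattern and stays open. These are 10 of the 18 NormalDuct regions, so every fold against NormalDuct depends on that label.

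Single regions that stood apart from the rest of their type were looked for in 185 groups of 4 to 10 regions, and 11 were found, where chance finds about 1 in 20 groups. The number found is close to that share, so each of these regions may stand apart by chance. In ADM, the highest region had 6.47 for HSPA1B against 5.98 for the next, 6.14 for GATA6 against 5.74 and 5.39 for DEFB1 against 4.59. The negative probes averaged 5.05 ± 0.04 in ADM (SD, n = 4 regions). DEFB1 lay below that background in the other ADM regions, so no difference in its expression can be read. In Nerve, the lowest region had 6.97 for TGFBI, 3.18 for PCNA, 0 for BHLHE41, 5.62 for ENG, 3.18 for LYZ, 5.02 for MGP and 4.10 for JCHAIN, and the highest had 6.49 for PECAM1 against 5.49 for the next. The negative probes averaged 5.19 ± 0.04 in Nerve (SD, n = 7 regions). The values of PCNA, BHLHE41, LYZ, MGP and JCHAIN lie below that background, so no difference in expression can be read from them.

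Region types in no comparison were set against the highest NormalDuct region. Both ChronicPanc regions held islet transcripts, with at least 15.75 for INS (highest NormalDuct region 10.57), 10.64 for CHGA (6.78) and 10.18 for PCSK1N (6.77). Both PanIN regions had at least 9.37 for CD55 (highest NormalDuct region 7.13), 10.85 for S100A11 (8.63) and 10.35 for S100A10 (8.36). These genes were picked as those farthest above NormalDuct.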

How the results depend on the processing

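Leaving out NormalDuct regions of plate 1 was chosen only after the result was seen, and all other alternatives were fixed before. The count for IPMN against NormalDuct was then 210, against 62 higher and 77 lower genes. Counts below are genes past the threshold, and where a count changed the cause was not tested, except that fewer slides or regions leave fewer columns to test. DESeq2 called 584 genes for IPMN against NormalDuct, 90 for Tumor against IPMN, 905 for Tumor against NormalDuct and 1062 for Acinar against NormalDuct. Limma-voom called 46 genes for IPMN against NormalDuct, 0 for Tumor against IPMN (857 had an unadjusted p under 0.05 with edgeR) and 1152 for Stroma against IPMN. A fit of only the 2 types called 5 (IPMN against NormalDuct), 41 (Tumor against IPMN), 43 (Tumor against NormalDuct) and 274 (Acinar against NormalDuct). With no replicate block for slide, the counts were 74 for IPMN against NormalDuct, 93 for Tumor against NormalDuct, 1887 for Stroma against IPMN and 339 for Acinar against NormalDuct, while Tumor against IPMN gave 8 either way. With regions as units, edgeR with slide as block, edgeR with plate as block and limma-voom called 2384, 2486 and 2621 for IPMN against NormalDuct, 1938, 1823 and 1781 for Tumor against IPMN, 3047, 3122 and 3145 for Tumor against NormalDuct, 7815, 7475 and 7910 for Stroma against IPMN, and 2099, 2030 and 1886 for Acinar against NormalDuct. Mean log2 levels per slide gave 31, 0, 174, 953 and 353 in the same order. Tumor against IPMN gave 16 genes with no filter and with filterByExpr, 3 with the negative probe value subtracted, 5 without columns of 1 region and 3 without low-quality regions. IPMN against NormalDuct gave 22 without columns of 1 region. Subtraction gave 1.4e+02 (to 2 digits) for Tumor against NormalDuct and 1116 for Acinar against NormalDuct. Lymphoid against Stroma gave 535 with no filter and 536 with filterByExpr. Leaving out 1 slide gave 1 to 255 for IPMN against NormalDuct, 0 to 17 for Tumor against IPMN, 1 to 423 for Tumor against NormalDuct, 1211 to 2592 for Stroma against IPMN and 1.1e+02 (to 2 digits) to 477 for Acinar against NormalDuct, the lowest without slide 3 in each. Leaving out 1 region of the smaller type (ADM, Nerve or Lymphoid), and none of Acinar or Stroma, gave 1003 to 1128 for ADM against Acinar, 702 to 779 for Nerve against Stroma and 217 to 561 for Lymphoid against Stroma. Without 1 Lymphoid region, the lone region of that arm is assumed to vary like Stroma. ADM and Nerve stayed within 1.5 times their counts under every alternative run, and the median-of-ratios and upper quartile scalings kept all 8 counts within that range.

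Lists past camera's threshold fell in number with an estimated correlation: 2 of 10 for IPMN against NormalDuct, 1 of 7 for Tumor against IPMN, 0 of 6 for Tumor against NormalDuct (10 with regions as units), 7 of 11 for Stroma against IPMN, 1 of 10 for Acinar against NormalDuct, 0 of 6 for ADM against Acinar, 4 of 10 for Nerve against Stroma and 0 of 7 for Lymphoid against Stroma.

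No named gene past the threshold changed its direction. The largest rises and falls were named for the same sign on every slide or for ranges that do not overlap, which favours this outcome. Of the values of the named genes past the threshold under alternatives, 460 of 607 stayed past it for IPMN against NormalDuct. Those that stayed and those that did not were 94 and 50 for Tumor against IPMN, 543 and 140 for Tumor against NormalDuct, 1325 and 57 for Stroma against IPMN, 730 and 162 for Acinar against NormalDuct, 804 and 55 for ADM against Acinar, 880 and 35 for Nerve against Stroma and 425 and 64 for Lymphoid against Stroma. Fixed genes that had not passed did so under an alternative in 19 cases for IPMN against NormalDuct, 20 for Tumor against IPMN and 17 for Tumor against NormalDuct. Such genes changed sign in 27 cases, and the cause was not tested. Between IPMN and NormalDuct, MUC6 was 0.0720 with DESeq2, 0.62 with limma-voom, 0.0342 with only the 2 types, 3.62 without slide 1 and 0.52 without NormalDuct of plate 1. MUC1 was 0.0195 with only the 2 types, 0.49 with no block, 0.42, 0.39 and 0.33 with regions as units, 0.90 without columns of 1 region and 1.27 without slide 2, and KRT17 was -0.31 without slide 1. Between Tumor and IPMN, MUC1 was 0.14 with regions in limma-voom and 0.21 with mean log2 levels, and CFTR was 0.0371 without slide 1. Between Tumor and NormalDuct, MUC2 was -0.0192 with upper quartile scaling, -0.14 and -0.18 with regions in edgeR (slide as block) and limma-voom, -0.0725 without columns of 1 region and -0.13 without slide 2. There MUC5AC was -0.0290 with limma-voom, and MUC1 was 0.22, 0.20 and 0.47 with regions as units, 0.76 without columns of 1 region and 0.76 without slide 2. Without each slide in turn, the range between IPMN and NormalDuct was -0.31 to 1.56 for KRT17, -2.43 to 3.62 for MUC6 and -1.27 to 1.27 for MUC1. It was -0.46 to 0.0371 for CFTR between Tumor and IPMN, and -0.13 to 0.30 for MUC2 and -1.28 to 0.76 for MUC1 between Tumor and NormalDuct. None of the 27 values passed the threshold.

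Depth limits which genes were tested: the median region had 15.41% of genes above its limit of quantitation, and 11358 of 18653 genes passed the filter for the sums. The slide sums of 2 types with 3 columns each make 10 splits, too few for a share under 0.05: the real split gave 62 higher and 77 lower genes for IPMN against NormalDuct and the highest other 1 gene, with 8 and 2 for Tumor against IPMN, 335 and 55 for Tumor against NormalDuct, and 3107 and 0 for Stroma against IPMN. For ADM against Acinar (1218 genes, highest other 358) and Nerve against Stroma (831, highest other 1.3e+02 to 2 digits), only the real 1 of 100 splits gave as many genes. Chance can be excluded there only if regions are independent, which the labels do not show, since regions may share donors.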

Other observations

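The test of depth in Lymphoid regions and the division of slide 3 in the KRT17 tests were chosen only after the result was seen, and the other tests of this part were written before their results, on patterns noticed in these data.

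IPMN regions of slide 3 fell into separate sets by gastric mucins. MUC5AC lay between 3.91 and 7.34 in 27 regions and between 9.67 and 13.79 in 32, with no region in the gap of 2.33, and MUC6 lay at or below 8.85 in 28 and at or above 10.85 in 31. For both genes 26 regions lay below and 30 above the gap, and 3 lay on different sides. The labels give no grade or subtype for these regions, so the sets are samples split by the data and were not compared.

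KRT17 was followed across IPMN regions against the mean of each list, without KRT17, and 2 quality measures in 88 relations, within slide 1, slide 2 and the 2 sets of slide 3, where the smallest p that 100000 permutations can give is 1e-05. On slide 1 KRT17 went with the genes of basement membrane and invasion, at Pearson r = 0.864 (n = 64 regions, permutation p = 1e-05, adjusted p = 0.00015) and Spearman rho = 0.88 (permutation p = 1e-05, adjusted p = 0.00011). It was 0.897 and 0.818 on plates 1 and 2 and 0.851 without the 2 regions farthest from the median KRT17. Other lists went with KRT17 on slide 1 as well, with r of 0.807 for keratins, 0.746 for the basal-like tumour list, 0.541 for hypoxia and glycolysis, 0.53 for immediate early and heat shock, 0.522 for the intestinal list and 0.478 for fibroblast matrix, and of -0.635 for the acinar and -0.395 for the B and plasma cell list (adjusted p from 0.00015 to 0.0073, and from 0.00011 to 0.012 for rho). The intestinal list had the opposite sign on slide 2, at -0.765 (adjusted p = 0.0044), which rests on the 2 farthest regions (rho = -0.11, adjusted p = 0.72, and r = 0.0977 without them). For the lists of interferon and antigen presentation (0.302) and classical tumour (-0.359) r passed but rho did not (adjusted p = 0.087 and 0.35), and the first was 0.12 on plate 1 and 0.813 on plate 2. The relation is thus not particular to 1 list, and the share of epithelium or stroma in a region was not separated from it. The acinar list averaged 5.38 ± 0.18 in IPMN of slide 1 (SD, n = 64 regions), near the background of 5.04 ± 0.07, although its member SPINK1 averaged 8.20 ± 1.05. Of single genes, GPRC5A had r = 0.841 and ITGB4 0.821 on that slide. On slide 2 r was 0.837 (n = 37, adjusted p = 0.00039, rho = 0.417, adjusted p = 0.062) and 0.27 without the 2 farthest regions, so it rests on those. On slide 3 r was 0.443 (n = 27, adjusted p = 0.073, rho = 0.0263, adjusted p = 0.94) below the MUC5AC gap and 0.257 (n = 32, adjusted p = 0.25, rho = 0.283, adjusted p = 0.33) above it. Without the 2 farthest regions these were -0.0312 and 0.0888, so the values of slide 3 rest on those regions and none passed. That KRT17 goes with this list in IPMN generally was put as a hypothesis that needed r above 0.3 on all 3 slides and above r with the cell cycle list. Slide 3 was divided into its sets only after the gap was seen. The lowest r of 0.257 lies under that bound, but its 95% confidence interval of -0.101 to 0.556 includes it. With the cell cycle list r was 0.246 on slide 1 (adjusted p = 0.11) and -0.406 on slide 2 (adjusted p = 0.043), but 0.497 and 0.634 in the sets of slide 3 (adjusted p = 0.029 and 8e-04). There it exceeded r with the basement membrane list, so that part of the hypothesis was not met in these sets. Below the gap the quality measures had r of -0.476 for background and 0.502 for the share of genes above the limit (adjusted p = 0.048 and 0.037). Their rho did not pass (adjusted p = 0.087 and 0.083), and above the gap neither r passed (adjusted p = 0.57 and 0.47). Region quality was not separated from the cell cycle relation below the gap. As put, r under 0.3 on any slide was to count against the hypothesis. It was not met in the set above the gap, but no r over all of slide 3 was computed. The hypothesis is thus not decided for that slide. The intervals of 0.366 to 0.805 and -0.101 to 0.556 in the set above the gap overlap, but intervals were not part of that rule. A relation with the basement membrane list on slide 3 is neither shown nor excluded. A further hypothesis was that KRT17 goes against the gastric mucous list on every slide. With this list r was -0.804 on slide 1 (rho = -0.744, adjusted p = 0.00015 and 0.00011), -0.388 on slide 2 (0.315 without the 2 farthest regions), and -0.327 and 0.225 in the sets of slide 3. It was thus not met in the set above the gap. The sets were divided by MUC5AC, a member of this list, which narrows the list's range within a set. No r over all of slide 3 was computed, so the hypothesis is not decided for that slide. KRT17 averaged 5.35 ± 0.61 on slide 2 and 5.40 ± 0.82 on slide 3 (SD), near the background of 5.05 ± 0.06 and 4.86 ± 0.16. Weak relations with any list on these slides therefore do not decide either hypothesis. Regions of a slide may share donors, so the p-values of all these relations are too small.

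Pancreatic enzyme transcripts were found outside Acinar regions of slide 3. Cross-talk between libraries of a plate is argued against, since Stroma on plate 4, which holds Acinar libraries, exceeded Stroma on plate 5, which holds none, by 0.69 in the acinar list (8.36 ± 1.34 and 7.66 ± 0.70, SD, n = 16 and 12 regions, permutation p = 0.112), below the bound of 1 set for it. NormalDuct and Tumor of plate 4 exceeded those of plate 1, which also holds Acinar libraries, by 2.77 (8.04 ± 0.74 and 5.27 ± 0.22, SD, n = 13 and 17 regions, permutation p = 1e-05). RNA from acinar cells in or beside the regions is a candidate source: across the 34 acinar genes, levels in NormalDuct of slide 3 followed those in Acinar of slide 3 with a rank correlation of 0.959, against 0.175 for NormalDuct of slide 1, where genes are not independent replicates. CPA1 and PNLIP averaged 11.34 and 11.70 in NormalDuct of slide 3, 16.38 and 16.50 in Acinar of slide 3, and 5.35 and 5.49 in NormalDuct of slide 1.

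Regions labelled Lymphoid held few transcripts of lymphocytes. Low depth was tested on B2M only, where 100% of the 30 Stroma regions of slide 1 thinned to the lower Lymphoid total stayed above both. B2M averaged 10.16 in these Stroma regions and thinning keeps a gene's expected level, so this outcome was fixed in advance. It shows only that depth does not lower B2M, and low depth was not tested for lymphocyte transcripts. Capture that left mainly background stays open: the 200 genes most abundant in the other regions of slide 1 lay at most 1.30 above background in Lymphoid, against 2.18 in the lowest Stroma region, while the share of genes above the limit was 7.87% and 18.2% against a Stroma median of 12.3%. A label that belongs to another type of slide 1 stays open too. The highest correlation reached by both with another type's profile was 0.142, against a median of 0.884 for held-out Stroma, but regions of mainly background would correlate with no type. No biological explanation was tested for it.

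In Tumor against NormalDuct, SGK1 and DUSP1, both induced by the glucocorticoid receptor, were lower, and a hypothesis was that other targets of the receptor are lower too. Over 8 other targets the median log2 fold change was -0.71, with 4 past the threshold, 7 negative and a camera p of 0.0256 with an estimated correlation, while in IPMN against NormalDuct it was -0.51 with 0 of 8 past the threshold and a p of 0.0446. Both comparisons use the same NormalDuct sums, so the second adds no independent evidence. GLUL differed by -1.10, FKBP5 by -1.15 and CEBPD by -1.17. This is consistent with lower transcripts of this target set in Tumor than in NormalDuct, as a hypothesis found on the same data. A like hypothesis for the histone genes beside H1-5 and H4C12 stays open, with a median of 0.65 over 56 genes, 8 higher, 53 positive and a camera p of 0.105 with an estimated correlation, where probes may not tell copies apart.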
